A study of Mus musculus with 4 samples.

How the data were processed

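Colon tissue of mice was profiled on 4 single-colour Agilent 4x44K arrays, 1 array for each combination of genotype and treatment. The mice are taken to be 9-week-old males, since the labels' age and sex tags appear to be swapped, and were either wildtype (WT) or lacking Pla2g10 (KO), the gene of group X secreted phospholipase A2. They were untreated (naive) or had received 1% (w/v) dextran sulfate sodium (DSS), which injures the colon lining and brings on colitis, in the drinking water until day 7. Per the labels, each array carried RNA mixed from the colons of 3 mice, so that no group holds a second array. Per the labels' protocols, Cy3-labelled copies were made from 200 ng of total RNA. All 4 arrays lie on 1 slide with 1 scan date, per the file headers.

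The deposited scanner files give, for each spot, an intensity after background subtraction and detrending (the processed signal), with flags for spots well above background, saturated spots and outlier spots. Agilent Feature Extraction 11.5.1.1 made these values, per the submitters' processing notes. The deposited series table holds a signal for each spot: the processed signal divided by the array's 75th percentile, per the file headers and the values themselves. Probe coordinates are those of the mm9 build, per the file headers.

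Each array had 43020 spots other than controls and 1377 control spots. Control spots and spots flagged as outliers were left out (129 to 136 spots per array), and 0 spots were saturated. The log2 processed signal was set relative to the 75th percentile of its array, so that a relative signal of 1 equals that percentile. Spots of the same probe were averaged on the log2 scale. Of 39429 probes, the 28719 that were well above background on at least 1 array were kept, and a gene was represented by its brightest kept probe. Symbols came from the files and from a RefSeq gene table of the GRCm38.p6 assembly, used for names only. Of the probes, 27508 were named by accession, 3544 by symbol, 404 by an older symbol, and 7973 kept the name in the file. This left 22161 genes, of which 18454 had a symbol and 19321 were well above background on all 4 arrays.

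With 1 array per group, 4 pairs of arrays were compared as log2 ratios with no test: WT DSS over naive, KO DSS over naive, KO over WT naive and KO over WT DSS. A gene was counted at a 2-fold threshold when it was well above background on the higher array. Where the lower array did not measure it, the lowest well-measured signal of that array took its place, and such folds are written as at least. The fit below and the list medians used the measured dim value in such cases, and the medians of neutrophil and pancreas markers are given with bounds too. Because each level of treatment and of genotype holds 2 arrays, the mean DSS effect and the mean genotype effect were also tested with an additive limma fit (lmFit and eBayes, limma 3.58.1 in R 4.3.3, with data.table version 1.17.8) with 1 residual degree of freedom and Benjamini-Hochberg adjusted p under 0.05. A response to DSS that differs between the genotypes enlarges the error of that fit. The difference of the DSS responses leaves no residual degree of freedom and is given as a value with no test. Tested on simulated data with 22161 genes, the fit of the DSS effect recovered 0% of changes of log2 1 and of log2 2, 74% at log2 4 and 88% at log2 6, with 3 false calls. For the genotype effect the shares were 0%, 0%, 76% and 90%, with 7 false calls. The simulation changed 50 genes of each size, each by the same amount at both levels of the other factor. These shares need not hold where more genes change or where the genotypes respond differently. The adjustment depends on all p-values, so with fewer large changes the shares at log2 4 and log2 6 can be lower.

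Before the data were examined, 37 gene lists (enzyme families, cytokine and chemokine genes, markers of the cell types a colon sample can hold, pathways and reference genes) and the genes within 10 Mb of Pla2g10 were fixed. For each list the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. Members were also tested in the additive fit with adjustment over the list alone, and not across the 37 lists. The rule for named genes was fixed at the same time. Among genes well above background on all 4 arrays, it takes the 12 genes with the largest rise and the 12 with the largest fall by the smaller of both genotypes' log2 ratios for the DSS effect, and 10 in each direction for the genotype effect. It adds 6 in each direction for KO over WT in naive mice and 10 for KO over WT with DSS, among genes well above background on both arrays compared, 6 for the difference of responses, up to 4 members of each list per comparison, and all phospholipases A2 and Th17 axis genes. Fewer than 12 and 10 genes passed the limma threshold, so those genes were taken without it.

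The alternatives were median scaling, quantile normalization, normexp background correction (offset 50) with quantile normalization, the authors' series table, probes well above background on all 4 arrays, no filter on dim probes, the mean of a gene's probes, no bound for unmeasured values, eBayes with trend and robust, a fit with 1 factor (2 residual degrees of freedom), that fit leaving out each array, and list means. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.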

Results

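The series asked how the loss of group X secreted phospholipase A2, an enzyme that releases fatty acids from phospholipids, changes the colon in DSS colitis. It holds 4 arrays, 1 per group, each of RNA pooled from 3 mice, so differences between single groups have no replicate check and carry no p-value. The share of spots well above background was 67.7% in WT naive, 68.6% in KO naive, 70.4% in WT DSS and 67.8% in KO DSS. Repeat spots of the same probe had a median SD of 0.0574 to 0.0635 on the log2 scale, which covers the noise within an array and not the spread between mice. The number of arrays limits the precision of all values.

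Pla2g10, the targeted gene (probe at chromosome 16, 13715169 to 13715228, mm9), had a relative signal of 15.9 in WT naive and 19.1 in WT DSS. In the KO pools it was 1.7 (naive) and 0.997 (DSS), log2 ratios of -3.23 and -4.26 against WT. Its fall in KO passed limma adjusted over the list of 22 measured phospholipases A2 alone (adjusted p = 0.025). It did not pass when adjusted over all genes. The direction matches the labels in both conditions, but whether the probe lies in the deleted part of the gene is not given in the sources used here, so the remaining signal cannot be read as intact transcript. Among its relatives, Pla2g2a, a secreted enzyme that kills bacteria, rose with DSS (log2 2.42 in WT and 2.84 in KO, adjusted p = 0.015 over the list alone). Pla2g5, another secreted member, was 2.31-fold higher with DSS in WT and 2.09-fold higher in KO (adjusted p = 0.056 over the list alone). With DSS, Pla2g7, which degrades platelet-activating factor, was 2.43-fold higher in KO than in WT, and Pla2g3 was 2.39-fold lower. The family as a whole had median log2 ratios of 0.03 and 0.03 with DSS in WT and KO.

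**Figure D1:**
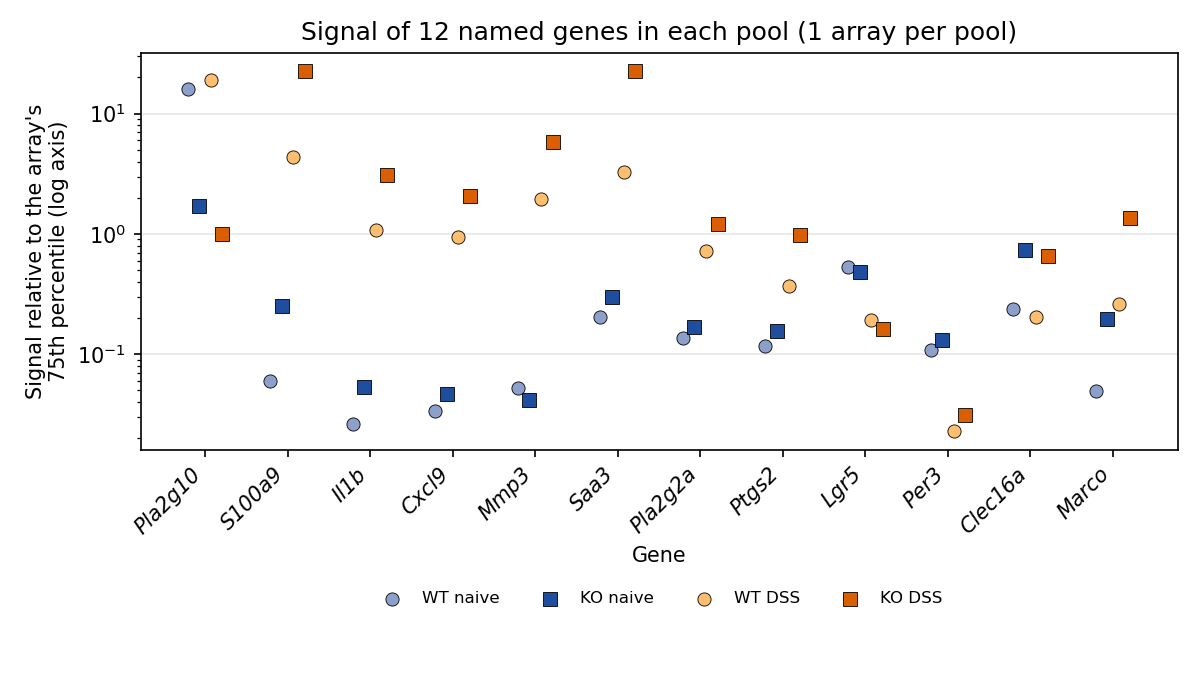
Signal of 12 named genes (x axis) relative to the 75th percentile of the array (y axis, log scale); each point is 1 array of RNA pooled from 3 mice, circles for WT and squares for KO, blue for naive and orange for DSS. Pla2g10 lies at 15.9 and 19.1 in WT against 1.7 and 0.997 in KO, and S100a9 goes from 0.06 in WT naive to 22.5 in KO DSS.

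DSS colitis was compared with naive colon in each genotype to see which genes respond to the injury. Among genes well above background on all 4 arrays, those furthest above naive in both genotypes included genes of recruited leukocytes, tissue-degrading enzymes and acute-phase proteins. S100a9, a calcium-binding protein of neutrophils, was 72.5-fold higher in WT and 88.4-fold higher in KO. The cytokine gene Il1b was 40.9-fold and 57.8-fold higher, and the stromelysins Mmp3 (37-fold and 138-fold) and Mmp10 (40.4-fold and 171-fold) were higher too. The interferon-induced chemokine genes Cxcl9 and Cxcl10 had log2 ratios of 4.79 and 4.54 in WT and of 5.47 and 4.40 in KO. Log2 ratios of the collagenase Mmp13 (3.94 and 5.87), the cytokine Il11 (4.15 and 5.60), haptoglobin (Hp, 5.01 and 6.26) and serum amyloid Saa3 (4.01 and 6.23) were of like size. The remaining genes among the top 12 of that set were Reg2 (5.91 and 4.33), of the regenerating islet-derived family, and the amylase gene Amy1 (5.12 and 4.22). Both rose more in WT than in KO, as did the pancreatic enzyme genes below, whose source stays open. Whether Reg2 and Amy1 belong with those genes was not tested.

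Neutrophil genes moved as a group: 13 of 21 measured markers rose with DSS by limma adjusted over the list alone. These included S100a8 (at least 113-fold higher in WT and 216-fold in KO, adjusted p = 0.00039), the lectin receptor Clec4e, at least 12.6-fold higher in WT and 61.2-fold in KO, and the receptor Cxcr2, which neutrophils use to follow chemokines (at least 2.18-fold and 7.28-fold). The list's median log2 ratio was 1.72 in WT and 4.07 in KO, and 1.23 and 2.86 with dim genes at their bounds. Of 27 chemokine genes 15 rose, among them Cxcl1, which draws neutrophils, at least 13.8-fold higher in WT and 41.2-fold in KO, and the monocyte attractant Ccl2 (mean log2 change 4.68). Of 23 inflammatory cytokine genes 11 rose, including Il6, which drives the acute-phase response, at least 20.5-fold in WT and 62.3-fold in KO, and Tnf (mean log2 change 3.11). Among 21 macrophage and dendritic cell markers, 11 rose, led by Chil3, a chitinase-like protein of activated macrophages (at least 49.2-fold in WT and 158-fold in KO), with Cd68 at a mean log2 change of 1.60, and Mertk, a receptor for clearing dead cells, fell by 0.82. Of 14 mast cell and eosinophil markers 8 rose, such as the mast cell proteases Mcpt1 (at least 2.75-fold and 8.25-fold) and Mcpt2 (at least 2.33-fold and 11.1-fold), and Kit fell by 0.81. In these lists and those that follow, 0 members passed adjusted over all genes tested.

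Interferon response genes rose in 16 of 32 cases by limma adjusted over the list alone. The GTPases Igtp and Gbp2, which act against intracellular microbes, had log2 ratios of 3.08 and 2.98 in WT and of 2.65 and 2.48 in KO. Ifng itself was at least 11.2-fold higher in WT and 13.7-fold in KO. It was among 6 of 14 Th1, Th2 and Treg genes that rose, while Il13, a type 2 cytokine, fell and was at least 4.87-fold lower in WT and 4.47-fold lower in KO. In the Th17 axis 4 of 13 genes rose: Il6, Il12b, Il22, which acts on the epithelium (2.5-fold and 2.89-fold), and the transcription factor Batf (2.72-fold and 5.05-fold). Il17a, the signature cytokine of that axis, had a relative signal of 0.0316 in WT DSS and 0.0928 in KO DSS and was not well above background in either naive pool (adjusted p = 0.13 over the list alone).

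The epithelium's own defence genes went both ways. Of 23 antimicrobial defence genes 10 rose, among them the bactericidal lectins Reg3b and Reg3g (mean log2 changes 2.65 and 3.31), the protease inhibitor Slpi (3.59) and the iron-binding Lcn2 (3.51), and 3 fell: the intelectin Itln1 (-2.22 in WT and -4.44 in KO), the angiogenin Ang4 and the antibody transporter Pigr. Crypt stem cell genes fell in 6 of 17 cases, including Lgr5, which marks these cells (-1.44 and -1.57), the transcription factor Ascl2 (-1.71 and -1.79) and the Wnt target Axin2 (-1.02 and -1.24). Absorptive colonocyte markers were lower in KO, with a median log2 ratio of -0.66 and 28 of 31 below 0, against -0.16 in WT (-0.57 and -0.32 with quantile normalization, and -0.01 in WT with median scaling), and 0 passed limma adjusted over the list alone. The chloride exchanger Slc26a3 stood at -1.21 in WT and -2.01 in KO. Goblet cell markers had medians of 0.18 in WT and -0.49 in KO, with Muc2, the main mucin of the colon, at -0.95 and -0.85, and 0 members passed. Smooth muscle markers were lower in both (medians -0.33 and -0.73), and Myh11, the smooth muscle myosin, and Casq2 fell adjusted over the list alone.

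Tissue remodelling genes rose in 8 of 31 cases adjusted over the list alone, among them Mmp3, Mmp10, Mmp13, the metalloprotease inhibitor Timp1 (mean log2 change 3.76) and the plasminogen activator Plau (2.02). Circadian clock genes fell in 9 of 18 cases and rose in 2 adjusted over the list alone; the hour of sampling is not given in the sources used here. The repressors Per1 (-1.81 in WT and -1.08 in KO), Per2 (-2.70 and -1.17), Per3 (-2.25 and -2.08) and Ciart (-2.15 and -2.72) fell, while Arntl, the activator of these genes, rose (0.88 and 0.79) as did Nfil3 (2.08 and 3.52). The other genes lowest in both genotypes among those well above background on all 4 arrays were Angptl7, a secreted angiopoietin-like protein (-2.41 and -2.53), Cubn, an uptake receptor (-1.82 and -1.94), Utrn, a relative of dystrophin (-1.86 and -1.73), Itih2, Glt1d1 and 4 genes known by systematic names, Gm20558, 5430427M07Rik, Gm7420 and D7Wsu130e.

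Genes of tissues other than the colon wall moved with DSS as well. Pancreatic enzyme genes rose in 9 of 14 cases adjusted over the list alone, with Amy2a5 (pancreatic amylase) at least 803-fold higher in WT and 272-fold in KO, and Cpa1 (carboxypeptidase) at least 178-fold and 31.7-fold. The list's medians were 5.14 and 3.01, and 4.97 and 2.48 with dim genes at their bounds. Adipocyte markers rose in 7 of 13 cases by the same adjustment, such as the fat cell hormone Adipoq (3.44 and 2.95) and the protease Cfd (3.39 and 3.14), and Pck1 fell. The haemoglobin genes Hba-a1 (1.16 and 3.18) and Hbb-bt (1.54 and 3.94) were higher, with 0 of 8 erythrocyte markers past adjustment over the list alone. Skeletal muscle markers had medians of -0.33 in WT and -1.38 in KO, and Myh2 and Actn3 fell by the same adjustment.

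Counted at 2-fold, 754 genes were higher and 1157 lower with DSS in WT, and 1257 were higher and 1106 lower in KO. At 4-fold the counts were 204 and 162 in WT and 419 and 169 in KO. The median of all genes was -0.02 in WT and -0.13 in KO, and median scaling moved that of WT to 0.12. The share of higher genes among those counted in WT was 39.5%, against 53.1% (952 higher, 841 lower) with median scaling and 52.9% (552 and 492) with normexp background correction and quantile normalization. In KO it was 53.2%, against 63.9% (966 and 545) with the latter and 49.5% (1489 and 1521) without bounds. In the additive limma fit, 0 of 22161 genes passed the adjusted threshold for the DSS effect (smallest adjusted p = 0.19), and 4088 had an unadjusted p under 0.05, where chance gives 1108. Limma made 1086 calls (446 higher, 640 lower) on probes well above background on all 4 arrays and 1532 (618 higher, 914 lower) with trend and robust. The prior degrees of freedom, the weight eBayes gives to the variance pooled over genes, were 2.17 in the main fit. They were 4.85 and a median of 6.51 in these alternatives, so the count of 0 depended on the filter and the variance model. The 24 genes named by rank passed in 24 and 19 cases in these alternatives, and 872 calls were shared. Those 24 were picked on the same arrays for large ratios in both genotypes, so their passing adds no support. Over the lists alone, 148 calls in 18 lists passed.

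**Figure D2:**
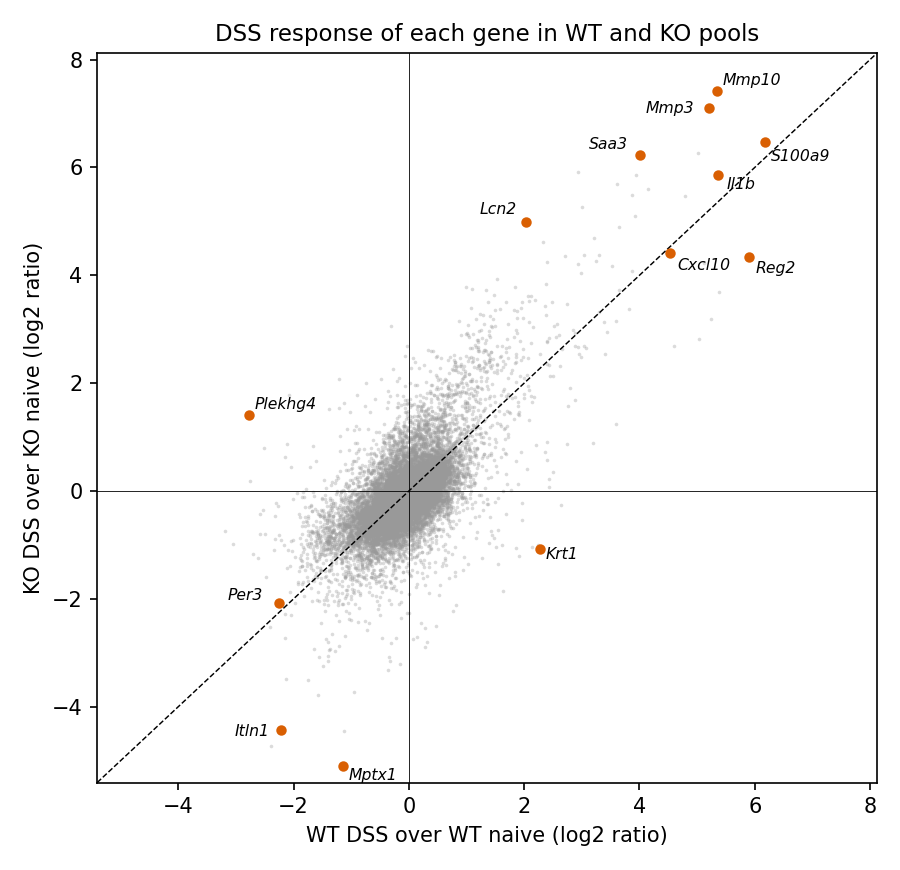
Log2 ratio of DSS over naive in WT (x axis) against that in KO (y axis) for 19321 genes well above background on all 4 arrays; each grey point is a gene, orange points carry names and the dashed line marks equal responses. Pearson's r across genes is 0.655; Mmp3, Mmp10, Saa3 and Lcn2 lie above the line, and Reg2, Krt1 and Mptx1 lie below it.

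In naive colon, KO was compared with WT for effects of the deletion without injury. A few markers of leukocytes were higher in KO in both conditions, while in naive colon the neutrophil list as a whole was higher in 12 of 21 cases (median log2 ratio 0.10) and macrophage markers in 11 of 21, both medians inside the range of the random lists. S100a9 was 4.24-fold higher in naive and 5.17-fold higher with DSS. Marco, a scavenger receptor of macrophages, was 3.98-fold and 5.14-fold higher, and Ltf, the iron-binding lactoferrin of neutrophil granules, 2.55-fold and 3.58-fold. Of 21 neutrophil markers 4, S100a8, S100a9, Ltf and Clec4d, rose with genotype over both conditions by limma adjusted over the list alone (adjusted p from 0.017 to 0.02). There was no adjustment across lists, and none of the 4 passed over all genes. The only other list with a genotype call was the phospholipases A2, through Pla2g10 itself. S100a8 was not well above background in WT naive, so its value there is a dim one. Sprr2d, a cornified envelope protein, was 5.1-fold and 5.81-fold higher, and Clec16a, which takes part in mitophagy, 3.05-fold and 3.22-fold. On the lower side, Retnla, a resistin-like protein of type 2 responses, had log2 ratios of -1.15 and -1.30, the eosinophil attractant Ccl24 -1.44 and -0.87, and the lectin Reg3a -0.94 and -1.17. S100g, a calcium-binding protein of the gut, stood at -0.76 in naive and -3.74 with DSS.

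B and plasma cell markers were higher in KO naive in 14 of 15 cases (median log2 ratio 0.57) and with DSS in 15 of 15 (median 1.03), Ms4a1 (CD20) being 1.76-fold higher in naive. Class II antigen presentation genes had medians of 0.44 and 1.12. Interferon response genes were higher in 31 of 32 cases in naive with a median of 0.26, and had a median of 0.15 with DSS. Endothelial markers were lower in KO naive in 13 of 14 cases (median -0.33), and matrix remodelling genes in 24 of 31 (median -0.22). The naive medians of these 5 lists lay outside the middle 95% of the random lists. In a count with 1000 random lists each, 11 of all 37 lists lay above that range in naive and 8 below it. Random lists were matched on expression only, and members of a list can vary together, so leaving the range is weak evidence. Among genes well above background on both naive arrays, those highest in the KO pool against WT were Pla2g4c, a cytosolic phospholipase A2 (15.2-fold), Depdc7, Olfr279, Gm10864 and Ins1 (insulin, 5.34-fold), and the lowest after Pla2g10 were St8sia3, Vmn1r240, Plekhg4, A130023I24Rik and Gm7550. Depdc7 had log2 ratios of 2.98 in naive and 0.12 with DSS, St8sia3 -2.97 and -0.02. Of the 22 measured phospholipases A2, Pla2g4c included, 0 rose with genotype over both conditions by limma adjusted over the list alone.

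At 2-fold, 250 genes were higher and 231 lower in KO naive. Limma found 0 genes for the genotype effect over both conditions (smallest adjusted p = 0.94), with 850 at an unadjusted p under 0.05 where chance gives 1108, and 5 calls in 2 lists adjusted over the lists alone. With trend and robust it called 7: S100a8, S100a9, Marco, Sprr2d, Clec16a, C130046B21Rik and AF144972, the last known by its transcript identifier. The counts in naive were 98 higher and 54 lower on probes well above background on all 4 arrays.

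With DSS, KO was compared with WT to see how the deletion alters colitis, and immune and matrix genes were higher in the KO pool. Retnlg, a resistin-like protein of neutrophils, was 9.16-fold higher, Fpr1, a receptor for bacterial peptides, 7.61-fold, Saa3 6.85-fold, and the protease inhibitor Serpina3m 7.77-fold. The others among the top 10 were 1810009J06Rik (10.3-fold), 5430431A17Rik, Gm5168, 4933417D19Rik, Bcl2l15 and the cilia gene Rsph4a. Neutrophil markers were higher in 17 of 21 cases (median log2 ratio 1.61), chemokines in 21 of 27 (median 1.01), inflammatory cytokines in 16 of 23 (median 1.12) and macrophage markers in 20 of 21 (median 0.89). Cxcl2, Il6 and Il1a, which is released by injured cells, were 4.58-fold, 2.84-fold and 3.28-fold higher. In the Th17 axis 12 of 13 genes were higher (median 0.57), with Il17a 2.93-fold and Batf 2.53-fold higher. Mast cell and eosinophil markers had a median of 0.94, with Mcpt1 4.11-fold higher, and Th1, Th2 and Treg genes one of 0.53. T and NK cell markers had a median of 0.55. With normexp background correction and quantile normalization the medians of the inflammatory cytokine, mast cell and eosinophil, and Th1, Th2 and Treg lists were 0.43, 0.47 and 0.28.

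Matrix remodelling genes were higher in KO DSS in 31 of 31 cases (median 0.89), among them Spp1 (osteopontin, 6.04-fold), the collagen cross-linking enzyme Lox (3.68-fold) and Mmp10 (3.64-fold). Endothelial markers were higher in 13 of 14 (median 0.76), led by Selp, the selectin that captures leukocytes (2.31-fold). Erythrocyte markers moved along with these groups and were higher in 8 of 8 cases (median 1.47), Hbb-bt being 4.95-fold higher. Of the eicosanoid genes, Ptgs2 (cyclooxygenase-2) was 2.63-fold and Alox5ap, needed for leukotriene synthesis, 2.33-fold higher. Ptgs2 had log2 ratios of 1.68 and 2.65 with DSS in WT and KO (adjusted p = 0.076 over the list alone).

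Several lists of epithelial genes were lower in KO DSS than in WT DSS. Absorptive colonocyte markers lay below 0 in 30 of 31 cases (median -0.49), with the water channel Aqp8 at -1.11 and Slc26a3 at -1.02. Goblet cell markers had a median of -0.33, fatty acid sensing and PPAR target genes one of -0.29, and tight junction genes one of -0.29. Oxidative phosphorylation genes, which are not particular to epithelium, were lower in 26 of 26 cases (median -0.33). Reference genes had a median of -0.18 here (-0.03 with quantile normalization) and all genes one of -0.09, so scaling may account for part of that count. With quantile normalization the goblet cell, tight junction and oxidative phosphorylation medians were -0.15, -0.15 and -0.15. Crypt stem cell genes had a median of -0.20, inside the range of the random lists, and antimicrobial defence genes were higher in 13 of 23 cases with a median of 0.06, which median scaling, moving all genes alike, turned to -0.03. Smooth muscle markers were lower in 16 of 18 (median -0.54). Pancreas markers were lower in 14 of 14 (median -2.29), with Pnlip (pancreatic lipase) at -3.25, Cela2a (elastase) at -2.67 and Cpa1 at -2.59. After Pla2g10, the lowest genes were S100g (-3.74), the pentraxin Mptx1 (-3.59), Pnlip, Gm5771 (-3.19) and Krt1, a keratin of stratified epithelium (-2.68), followed by Igsf11, Ttc21a and the pancreatic genes.

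At 2-fold, 1127 genes were higher and 486 lower in KO DSS, a higher share of 69.9%, and the median of all genes was -0.09. Apart from crypt stem cell genes, and leaving aside the reference genes, the lists in these paragraphs on KO DSS had main-analysis medians outside the middle 95% of the random lists. Of all 37 lists, 18 lay above that range and 12 below it, counted with 1000 random lists each, so leaving it was common. On probes well above background on all 4 arrays the counts were 736 and 247, with normexp background correction and quantile normalization 547 and 267, with median scaling 923 and 561 (62.2% higher) and without bounds 1276 and 908 (58.4%).

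**Figure D3:**
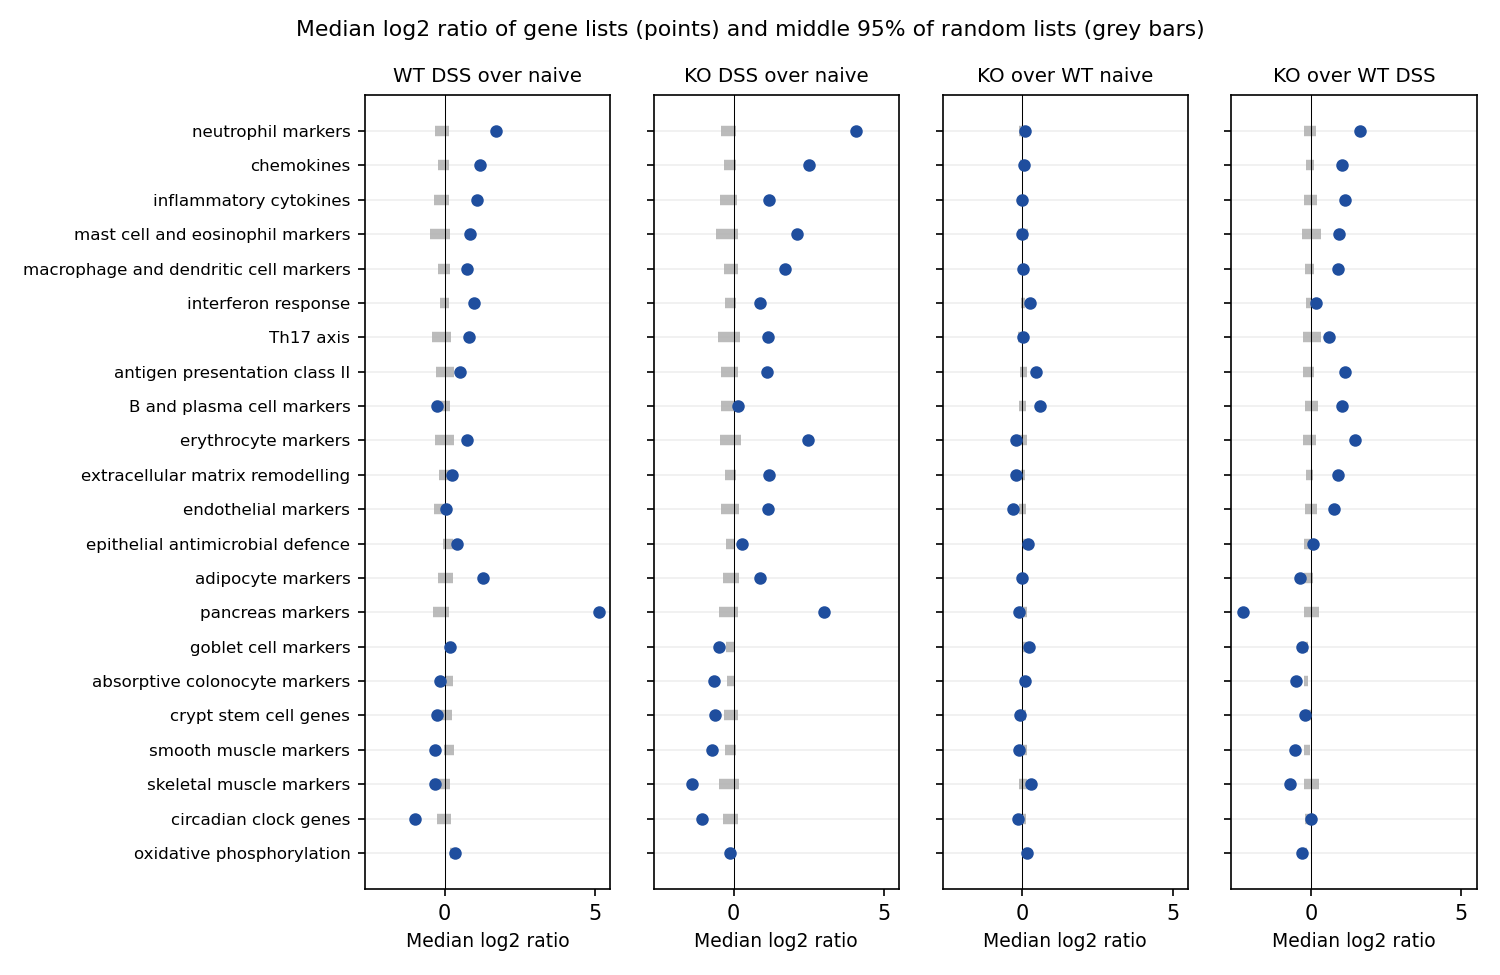
Median log2 ratio (x axes) of 22 gene lists (y axis) in the 4 comparisons; points are the medians and grey bars the middle 95% of medians of 10000 random lists matched on mean expression, with 1 array per group. Neutrophil markers lie at 1.72 (WT DSS over naive), 4.07 (KO DSS over naive), 0.10 (KO over WT naive) and 1.61 (KO over WT DSS), and pancreas markers at 5.14, 3.01, -0.11 and -2.29. The points use measured dim values. With dim genes at their bounds, the Th17 axis goes from 0.80 to 0.11 in WT DSS over naive and from 1.16 to 0.57 in KO. Matrix remodelling goes from 0.26 to 0.03 in WT DSS over naive, and mast cell and eosinophil markers from 2.12 to 1.37 in KO DSS over naive.

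The DSS responses of the genotypes were set against each other to see where the deletion alters the response. Lcn2, which withholds iron from bacteria, had a log2 ratio of 2.03 in WT and 4.99 in KO, and Serpina3n, a protease inhibitor of the acute phase, 2.94 and 5.92. Mptx1 went from -1.14 in WT to -5.11 in KO, and the immunoglobulin kappa segment Igkv9-129 from -2.11 to 0.87. Across genes, which are not independent replicates, the responses had a Pearson correlation of 0.655 (Spearman 0.603), and 70.9% had the same sign. Among the 19321 genes well above background on all 4 arrays, 490 were 2-fold higher in WT and 911 in KO, with 335 in both where independent lists would share 23.1, and 779 and 805 were lower, with 271 in both against 32.5. The log2 ratio was higher in KO by at least 1 for 697 of these genes and lower for 405. The difference was not tested. Genotype differences in naive and DSS pools had a Pearson correlation of 0.0356 (Spearman -0.08), with 29 genes higher in KO at 2-fold in both (3.73 if independent) and 3 lower (0.69).

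Genes near Pla2g10 were examined because a targeted allele can carry flanking sequence of another strain. Of 235 measured genes within 10 Mb, 5 differed at least 2-fold in the same direction in both conditions (2.13%), against 1 of 385 on the rest of the chromosome (0.26%) and 24 of 18463 elsewhere (0.13%). Clec16a, 2.97 Mb away (10744705 to 10744764), was one of them. The others, chosen after their values were seen and known by transcript identifiers alone, were AK163054 (2.43-fold and 2.76-fold higher in naive and DSS) and AF138742, S79427 and ENSMUST00000103749, which lie at the immunoglobulin lambda locus. The median of the neighbourhood's 265 genes was 0.03 in naive and -0.10 with DSS.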

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

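The test on acinar genes was set out before their values were seen; the other tests in this part were chosen only after the results were seen. Krt1, Lor and Lce3a, genes of stratified epithelium, went in opposite directions with DSS: log2 ratios of 2.27 in WT and -1.07 in KO, 1.86 and -1.05, and 1.64 and -1.85. Apom, an apolipoprotein, stood at 2.14 and -1.05, Plekhg4 at -2.77 and 1.42, and Rsph4a at -1.21 and 2.08. Between genotypes, Lce3a was 1.09 in naive and -2.4 with DSS (log2 of KO over WT), and the skeletal muscle genes Myh1 (1.42 and -1.92) and Tnnc2 (1.07 and -1.88) turned likewise. Plekhg4 was -2.79 in naive and 1.39 with DSS. In all, 10 genes were at least 2-fold higher with DSS in WT and lower in KO and 9 the other way, fewer than the 20.4 and 36.7 that independent lists would share, while 10 were higher in KO in naive and lower with DSS and 5 the reverse. With 1 array per group, none of these differences was tested.

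Pancreatic enzyme genes rose with DSS in 9 of 14 cases. If pancreatic tissue or its RNA had entered the DSS pools, acinar genes outside the list should be high too: 54.5% of 11 measured were at least 2-fold higher in WT DSS, too few to settle it and too many to set it aside. Try4 and Try5 were at least 284-fold and 306-fold higher, and of the 5 that missed 2-fold, Sycn and Spink1 had a strong signal in the naive colon (76.7 and 38.3) that would hide a small addition, Serpini2 lay at the floor in WT naive, Erp27 went from 1.11 to 1.5, and Pnliprp2 (0.0915 in WT naive and 0.062 in WT DSS) goes against it. The test scored WT alone. In KO DSS over naive, Try4 and Try5 alone reached 2-fold (log2 at least 5.69 and 5.89). Sycn and Pnliprp2 fell there (-2.05 and -2.04). The 12 list members that were 2-fold higher in WT DSS were lower in KO DSS (median log2 ratio -2.35, SD 0.447). So were the 6 such genes outside the list (-1.64, SD 0.638). Picking genes high on the WT DSS array leans these ratios downward. Outside the list, genes that missed 2-fold were lower in KO DSS too, from -0.08 (Pnliprp2) to -1.57 (Sycn). Tissue carried over and induction in the inflamed colon cannot be told apart, the latter being untested.

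Immune and matrix genes were higher in the KO DSS pool than in the WT DSS pool. More blood could account for the neutrophil genes, since erythrocyte markers were higher by a median log2 ratio of 1.47, but the 14 members of the matrix list that fibroblasts and not blood cells make had a median of 0.855 (SD 0.448, 14 above 0) and argue against it as the cause there. A lower epithelial share, with the other layers kept in proportion, would raise matrix and smooth muscle markers alike. Their medians lay 1.43 apart, more than their summed SDs of 1.19, which argues against that simple form. The test cannot exclude a lower epithelial share with a changed mix of the other layers. Array scaling does not account for the matrix genes, whose median was 0.945 with quantile normalization. More blood stays open for the neutrophil genes, and a changed mix of tissue layers for the immune and matrix genes. Whether genotype or a difference in colitis severity between pools set the pattern is open too. With 1 pool of each genotype and condition, genotype and severity cannot be told apart. Genotype therefore remains a hypothesis.

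Of 235 measured genes near Pla2g10, 5 were at least 2-fold higher in both KO pools. For the 3 at the immunoglobulin lambda locus (within 1 Mb of Iglv1), more B and plasma cells in the KO pools are a candidate explanation: 130 genes in the heavy and kappa chain regions of other chromosomes had a median log2 difference of 0.406, with 101 above 0, though only 2 of them were 2-fold higher in both conditions, against 3 of 40 at the lambda locus. That leaves 2 of 195 genes, Clec16a and AK163054, against 24 of 18463 on other chromosomes (Fisher's exact two-sided p = 0.03). Passenger sequence around the targeted allele may lie behind these, but 2 genes are too few to tell, and the strain of the targeted cells is not given in the sources used here. No biological effect of Pla2g10 on Clec16a was tested.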

How the results depend on the processing

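All alternatives here were set before the data were examined. Median scaling and quantile normalization left every pair count within 1.5 times and 0 calls in both limma tests. The authors' series table did too, but it is scaled as the main analysis is, so its agreement was fixed in advance. Median scaling cannot change correlations, spot noise or a list's place among random lists. Of 178 values that counts and correlations took under the alternatives, 150 held, 23 of them from the series table. Normexp background correction with quantile normalization gave 492 genes lower in WT DSS (1157), 545 lower in KO DSS (1106), 137 higher and 123 lower in KO naive (250 and 231), 547 and 267 in KO DSS against WT DSS (1127 and 486) and 421 and 241 for the difference of responses (697 and 405); its spot noise was 0.193 against 0.0603. Probes well above background on all 4 arrays, which removes genes measured on fewer, gave 490 higher in WT DSS (754), 98 and 54 in KO naive, and 736 and 247 in KO DSS against WT DSS. Without bounds the counts were 446 and 447 in KO naive and 908 lower in KO DSS against WT DSS. The limma count for DSS, 0, became 1086 on those probes, 13 with no filter on dim probes and 1532 with trend and robust; for genotype it became 7 with trend and robust. In leave-one-out fits with 1 factor the DSS count ranged from 0 to 736, with 736 without WT DSS, 92 without KO DSS and 0 without either naive array, the lone array being assumed to vary like the others; the genotype count stayed 0. The correlation of DSS responses (0.655) was 0.673 with quantile normalization, 0.702 with normexp and 0.643 with the mean of a gene's probes, and that of genotype differences (0.0356) 0.0539 and 0.0523 with the first 2. Bhlhe41, measured in WT naive alone, turned with no filter on dim probes. WT DSS over naive went from -3.32 to 0.12, KO over WT DSS from 1.42 to -0.47 and the difference of responses from 2.22 to -0.235. Since neither DSS pool measured this gene, the last 2 values have no readable direction, and -3.32 rests on a dim value. No other named gene at 2-fold turned sign. Of the named genes' values, 5654 moved less than spot noise (0.085, for the ratio of 1 gene) and 1662 more. Of those 5654, 1079 came from the series table. By the same limit 932 of 1216 values of list medians moved less, 152 of them from the series table, but that limit is loose for a median of many genes. With normexp and quantile normalization the median of neutrophil markers was 1.01 in WT DSS over naive and 2.27 in KO (1.72 and 4.07), and in KO over WT DSS that of inflammatory cytokines was 0.43 (1.12), of mast cell and eosinophil markers 0.47 (0.94) and of Th1, Th2 and Treg genes 0.28 (0.53). Calls over the lists alone numbered 131 to 233 for DSS (148) and 5 to 37 for genotype (5). The cause was not tested. Leaving out saturated probes was void (0 spots), and a slide block was not run (1 slide). Signal near background limits the dimmest genes: 2840 were well above it on 1 to 3 arrays.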

Other observations

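Several gene groups have no place in the comparisons above. Cell cycle genes were higher with DSS in WT in 24 of 26 cases (median log2 ratio 0.68) and had a median of 0.07 in KO, with Rrm2, a ribonucleotide reductase subunit, at 1.15 and 0.74 and Birc5 (survivin) at 1.00 and 0.28. Their KO over WT medians were 0.32 in naive and -0.23 with DSS, so part of that difference lay in the naive pools. Enteroendocrine and tuft cell markers were lower in KO DSS than in WT DSS in 17 of 19 cases (median -0.37), while Dclk1, a kinase of tuft cells, stood at 1.14. Enteric nerve and Cajal cell markers had medians of -0.14 in WT and -0.02 in KO, both of which change sign with median scaling, which moves all genes alike, with the glial filament Gfap at 1.08 and 2.04 and the neuropeptide Vip at 0.21 and 1.56. Unfolded protein response genes stood at 0.34 and 0.48, with Chac1, which degrades glutathione, at 1.03 and 1.21, and hypoxia and glycolysis genes at 0.25 and 0.13, with Pfkfb3, a regulator of glycolysis, at 1.24 and 1.71. Immediate early genes had medians of 0.37 and 0.20, with Egr2 at 1.89 and 1.42. In all of these lists 0 members passed limma adjusted over the list alone.

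Stratified squamous markers had medians of 0.73 with DSS in WT and -0.28 in KO, with the basal keratin Krt5 at 0.80 and 1.80. Reference genes stood at 0.38 in WT and -0.12 in KO, the latter turning to 0.02 with another scaling, with Gapdh at 0.57 and -0.21. Of 4 measured sex-linked genes, Kdm5d fell with DSS adjusted over the list alone (adjusted p = 0.019) and was at least 2.21-fold lower in WT and 2.01-fold in KO, while Ddx3y stood at -0.32 and -0.27. The list's medians were -0.21 and -0.54. Other probes of the same gene, where it had any, went the same way as the brightest for 90.4% of 219 genes at 2-fold with DSS in WT and for 90.3% of 360 in KO, and reached 2-fold for 49.3% and 59.7%. For KO against WT the shares were 81.8% of 11 genes in naive and 83.3% of 203 with DSS, with 27.3% and 53.2% at 2-fold.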
